A study of Mus musculus with 3 samples.

How the data were processed

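Mandibular condyles, the jaw side of the temporomandibular joint, were taken from wild-type mice at embryonic day 16.5 (E16.5), at birth (P0) and at 13 weeks of age (13w). Per the labels' protocols, tissue from 7 to 20 mice was pooled within each age group and digested with collagenase and dispase, live cells (Calcein positive, DAPI negative) were sorted, and each pool became a single droplet library with the 10x Genomics 3′ chemistry. There is thus 1 library per stage and no replicate.

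The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.2 per the file headers, on genome build GRCm39 per the submitters' processing notes. No normalisation had been applied, and barcodes had already been limited to called cells. The files pair each gene identifier with a symbol, and those symbols are used throughout. The reference held for this work is of an earlier mouse build, so no coordinates are given. The antisense and near-identical gene pairs of the annotation were not resolved further, and Bglap with Bglap2, Hspa1a with Hspa1b, and the H2 class I genes are pairs or families that share sequence.

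The starting point was 5458 barcodes with 103827875 UMIs at E16.5, 4853 with 98486931 at P0 and 8899 with 115836876 at 13w. Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. The mitochondrial limit removed 15.4% of barcodes at E16.5, 16.5% at P0 and 9.21% at 13w. Doublets were scored per library with Scrublet as run through scanpy 1.11.5. Its automatic threshold marked at most 0.11% of cells in any library and was taken not to have worked. The highest-scoring cells were removed instead, at about the share expected from loading, 0.8% per 1000 cells. Cells tied at the cutoff score were removed too. This took out 174, 134 and 548 cells at E16.5, P0 and 13w, or 3.81%, 3.35% and 6.83%, against 3.65%, 3.20% and 6.42% expected. This left 4388, 3865 and 7480 cells.

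Cells were scaled to 10000 UMIs, log-transformed and clustered together without integration on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Genes of the fixed lists that are not cell type markers were left out of the clustering features. Clusters were named from fixed markers of 24 cell classes. A cluster needed at least 3 detected markers, and the size of marker enrichment that earned a name was set after the data had been seen. Clusters without blood, vascular, muscle, neural or epithelial identity form the skeletal-lineage cells. Within these, clusters named chondrocyte or hypertrophic chondrocyte form the chondrocyte family, and clusters named superficial fibrocartilage or fibroblast form the surface and fibroblast family.

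Raw counts were summed per library within skeletal-lineage cells and within each family, and divided by the total and scaled to give CPM, the share of all counts on the usual fixed scale. A gene counted as measured with at least 10 CPM in the higher library, and as higher or lower with a ratio of at least 2 whose counting interval excluded 1. Intervals are 95% and exact (Poisson for sums, conditional binomial for ratios, Clopper-Pearson for shares). They cover counting error only, and neither animal-to-animal nor library-to-library variation. Where a library held no count of a gene, the ratio was taken against a floor of 3 counts and is a lower bound. With 1 pooled library per stage no test was possible, and no difference between stages has a replicate check.

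Before the data were examined, 23 gene lists were fixed. They cover the cell cycle, cartilage matrix, hypertrophy and mineralisation, joint surface, fibrous matrix, hedgehog and Pthlh, Wnt, BMP and TGF-beta, FGF, Notch, the IGF axis, an imprinted growth network, proteases and inhibitors, progenitor candidates, jaw patterning transcription factors, mechanoresponse, immediate early and heat shock genes, glycolysis and hypoxia, antigen presentation and interferon, inflammatory and complement genes, DNA maintenance and senescence, haemoglobin, and myeloid granule genes. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The cartilage matrix list shares 12 of its 22 genes with the cell type markers, the hypertrophy list 10 of 18, the joint surface list 7 of 15, the progenitor list 11 of 30, and fibrous matrix 8 of 25. The progenitor list also shares 6 genes with other lists.

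The genes named were fixed by rule at the same time. For P0 against E16.5 and for 13w against P0 in skeletal-lineage cells, these are the 10 genes with the largest ratio in each direction among those with at least 100 CPM in the higher library and no higher level in the other cells of that library. Mitochondrial, ribosomal protein, haemoglobin, Y-linked, Xist or Tsix, immunoglobulin and predicted genes were left out of that choice. From each list, up to 3 members with the largest ratio are added. Not every gene picked by this rule is reported here. Other genes named were chosen after their values were seen, including those of the comparison between families and those named within a family.

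Shares of cells with a UMI were compared after thinning each cell to 3000 UMIs and leaving out shallower cells. Alternatives covered the cell filters, doublet removal, cluster resolution, clustering each library alone, trimmed mean of M-values (TMM) factors (edgeR 4.0.16 in R 4.3.3, used for these factors only), median-of-ratios size factors, CPM minimums of 1 and 50, mean per-cell CPM, thinned cells, equal weight per class, leaving out genes higher in other cells, and, chosen after seeing the data, leaving out the cycling clusters. Equal weight per class averages the CPM of the chondrocyte family, the surface and fibroblast family and the unnamed skeletal cells, and leaves cluster shares within each as they are. The calling step was tested on counts simulated from the real libraries with 200 altered genes per comparison. In P0 against E16.5 in skeletal cells it called 67 of 67 genes altered 3-fold, 66 of 66 altered 6-fold and 0 of 67 altered 1.5-fold, with 0 calls among 7632 unaltered genes. In the surface and fibroblast family 8 of 8511 unaltered genes were called for P0 against E16.5 and 5 of 7851 for 13w against P0. Both simulated libraries were drawn from the shares of 1 library with counting error only, without library, animal or cell makeup variation. The outcome thus checks the calling rule and gives no rate of false calls between real stages. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.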

Results

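Single-cell RNA was counted in condylar cartilage of the mouse jaw joint at 3 stages, E16.5, P0 and 13w, with 1 pooled library each. The stages span the opening of the upper joint cavity, the first use of the joint and the adult joint. The study asks which cells are skeletal progenitors and how zones are laid out in the condyle. After filtering, 4388 cells at E16.5 had a median of 17230.5 UMIs, 3865 cells at P0 had 17396, and 7480 cells at 13w had 10684. Mice were pooled and each stage has a single library, so every difference below compares 3 libraries and has no replicate check.

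Nearly all cells belonged to the skeletal lineage, with small numbers of vascular, muscle and blood cells beside them. Clusters named endothelial, mural, muscle, monocyte, neutrophil, B cell and erythroid stood apart, beside an unnamed blood cluster of 94 cells. Neutrophils were mostly in the adult library. The cluster named monocyte had the mast cell protease genes Cma1 and Cpa3 among its leading genes, so its name may not cover all its cells. Some skeletal clusters were named into a chondrocyte family or a surface and fibroblast family, and more than 50% of skeletal cells at every stage matched no fixed class. Skeletal-lineage cells made up 93.2% at E16.5 (95% interval 92.4 to 93.9), 97.0% at P0 (96.4 to 97.5) and 95% at 13w (94.5 to 95.5). Endothelial cells were 1.09%, 0.854% and 0.307% of cells, and neutrophils were 2.09% of cells at 13w. Live-cell sorting and the mitochondrial limit both act on these shares.

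The chondrocyte family held 20.4% of skeletal cells at E16.5 (19.2 to 21.7), 41.8% at P0 (40.2 to 43.4) and 25.5% at 13w (24.5 to 26.5). The surface and fibroblast family held 21.2% (20.0 to 22.5), 6.53% (5.76 to 7.37) and 15.2% (14.4 to 16.1). Unnamed skeletal cells were 58.4%, 51.7% and 59.3%. No order between stages is read from these shares, because 17 of the 20 skeletal clusters drew over 90% of their cells from 1 library. At E16.5 the chondrocyte family lay mainly in clusters of 383 and 434 cells named chondrocyte, and at P0 in clusters of 710 and 852 cells, the first of them shared with E16.5. At 13w it lay in clusters of 1092 and 718 cells named hypertrophic chondrocyte, the second of which also expressed the bone genes Bglap and Bglap2. The surface and fibroblast family was a fibroblast class at E16.5 (688 cells and a cycling cluster of 176) and at P0 (194, 38 and 13 cells), and a superficial fibrocartilage class at 13w (1079 cells).

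Summed over all skeletal cells, the P0 library held more cartilage matrix transcript and less proliferation transcript than the E16.5 library, by smaller amounts when cell classes weigh equally. P0 skeletal cells had more transcript for the cartilage proteoglycan Acan, the load-bearing matrix proteins Comp and Chad, the collagen-organising Fmod, and the mineral-binding protein Spp1. They had less transcript for replication genes such as Mcm3, Rrm2 and Pclaf, for the Wnt-binding Sfrp2, for the retinoic acid-binding Crabp1, and for the growth factor Igf1. Some mechanically responsive genes were higher, among them the matricellular Ccn2, the cation channel Trpv4 and the prostaglandin enzyme Ptgs2. Of 8184 genes measured, 458 were at least 2-fold higher and 699 lower at P0. The higher genes were 39.6% of the calls, against 56.3% with TMM factors and 55.5% with median-of-ratios factors, which move the median log2 ratio up by 0.14.

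Among the genes named by the fixed rule, Spp1 stood at 1645 CPM at P0 against 185 CPM at E16.5 (log2 3.15, counting interval 3.13 to 3.17), Fmod at 377 against 42.7, Comp at 994 against 242, Ccn2 at 286 against 64.6, and the ecto-nucleotidase Nt5e at 235 against 57.3. Anxa8 was 6.64-fold higher, Vldlr 5.82-fold, Scrg1 4.56-fold, Loxl3 4.13-fold and Sdc4 4.01-fold. Lower at P0 were Sfrp2 at 25.8 CPM against 279 (log2 −3.44, −3.50 to −3.38), Crabp1 by 9.21-fold, Pclaf by 4.96-fold and Igf1 by 4.16-fold. The midkine gene Mdk, the embryonic transcription factor gene Sox11, Angptl1, Mfap4, Hspd1 and Snrpd3 were lower by 3.53-fold, 3.42-fold, 3.38-fold, 3.16-fold, 3.14-fold and 3.07-fold.

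**Figure D1:**
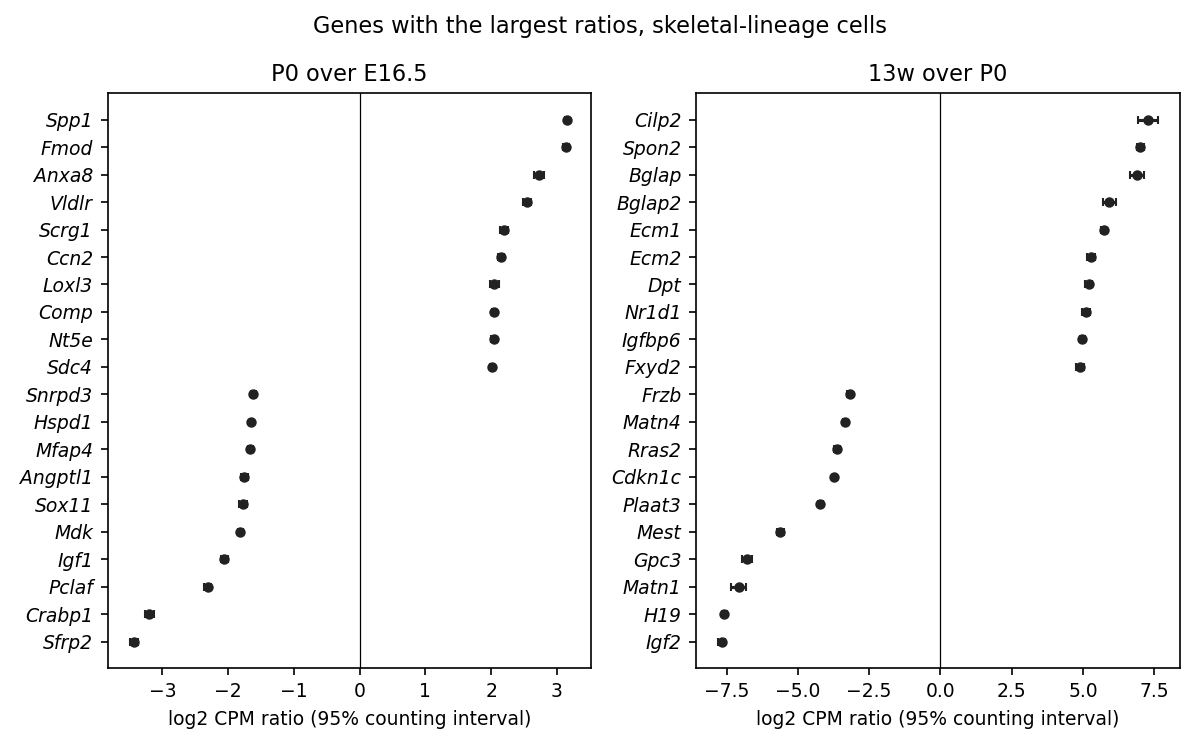
Log2 CPM ratio in skeletal-lineage cells of 20 genes with the largest ratios among those with at least 100 CPM in the higher library and no higher level in its other cells, for P0 over E16.5 and for 13w over P0; bars are 95% counting intervals. Spp1 (3.15) and Sfrp2 (−3.44) lie at the ends of the first comparison, and Cilp2 (7.27) and Igf2 (−7.67) at the ends of the second.

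Structural genes of cartilage were higher at P0 as groups, in part with the differing makeup of the libraries. Of 21 cartilage matrix genes measured, 16 were higher and 0 lower (median log2 1.25, above all 10000 random lists), led by Chad (78.4 against 3.90 CPM), Comp and Acan (3.12-fold). With equal weight per class 3 of 20 were higher and 0 lower (median 0.51), and within the chondrocyte family 4 of 21 were higher and 0 lower (median 0.60). Hypertrophy and mineralisation genes were higher in 8 and lower in 1 of 15 (median 1.06; 4 and 0 of 15 with equal weight, median 0.69), with Mmp13 10.0-fold and Mgp 4.00-fold higher. Fibrous matrix genes were higher in 10 and lower in 5 of 25 (median 0.76), with Fn1 3.88-fold higher and Col14a1 9.27-fold lower. Joint surface genes went both ways in the sum over all skeletal cells, 2 higher and 3 lower of 11 (median 0.29), with Crip2 2.70-fold higher, Abi3bp 4.99-fold lower and Vcam1 2.55-fold lower. With equal weight per class 6 were higher, 1 lower and 6 neither of 13 (median 0.82). Within the surface family the split was likewise 6, 1 and 6 of 13 (median 0.75), and in chondrocytes 3 were higher, 0 lower and 4 neither of 7 (median 0.82). Proteases and inhibitors were higher in 2 and lower in 1 of 11 (median 0.41), with the aggrecanase Adamts5 5.02-fold higher, Timp1 2.82-fold higher and Mmp16 2.11-fold lower.

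Signalling genes were mostly within 2-fold between E16.5 and P0. BMP and TGF-beta genes were higher in 7 and lower in 2 of 25 (median 0.26), with Tgfb1 4.96-fold and Bmp2 3.74-fold higher and Ltbp2 3.20-fold lower. Wnt genes were higher in 2 and lower in 5 of 19 (median −0.20), with Rspo3 and the receptor Lgr5 7.22-fold and 6.73-fold lower. In the hedgehog and Pthlh list 0 were higher and 2 lower of 11, the hedgehog co-receptor Gas1 by 5.70-fold and the growth plate signal Pthlh by 2.34-fold, and Pthlh goes the other way when cell classes weigh equally. FGF genes were higher in 0 and lower in 1 of 7 (median 0.49), with Fgf18 2.05-fold lower and Fgfr1 short of 2-fold (log2 0.94). No FGF gene was higher or lower with equal weight per class (median 0.17) or with thinned cells (0.24), and both medians lay inside the random range. The Notch list had 3 measured genes, none past 2-fold (median 0.25, with Hes1 at 0.47). IGF axis genes were higher in 3 and lower in 4 of 12, with Igfbp6 2.93-fold higher and Igfbp2 4.38-fold lower. The imprinted growth network was higher in 0 and lower in 2 of 13 (median −0.35), namely Igf2bp1 by 2.32-fold and Dlk1 by 2.05-fold, while Plagl1 stood just short of 2-fold higher (log2 0.99). Dlk1 goes the other way with equal weight per class. The medians of the hedgehog (−0.06), IGF (−0.12) and progenitor (−0.08) lists take the opposite sign with TMM factors. With equal weight per class they stood at 0.25, 0.36 and 0.61, and that of the imprinted network at 0.11, also of the opposite sign. With thinned cells the hedgehog, Wnt, Notch and progenitor medians took the opposite sign, so no direction is read for these lists between E16.5 and P0 in all skeletal cells.

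Among the remaining groups, progenitor candidates were higher in 6 and lower in 4 of 22 in the sum over all skeletal cells, but in 10 and 1 of 25 with equal weight per class. Within families they were higher in 7 and lower in 0 of 15 (chondrocytes) and in 9 and 1 of 24 (surface). In the sum, the transcription factor gene Foxa2 was 4.63-fold and Nt5e 4.10-fold higher and the niche factor Cxcl12 8.36-fold lower. Jaw patterning transcription factors were higher in 0 and lower in 2 of 9 (median −0.67), namely Osr1 by 10.5-fold and Dlx6 by 3.48-fold. The split was the same with equal weight per class, but the median (−0.39) lay inside the random range. Mechanoresponse genes were higher in 4 and lower in 0 of 15 (median 0.55), with Ptgs2 4.59-fold and Trpv4 2.30-fold higher. Immediate early and heat shock genes were higher in 0 and lower in 1 of 19 (median 0.41), the heat shock gene Hsph1 by 3.40-fold. Glycolysis and hypoxia genes were higher in 1 and lower in 3 of 19 (median −0.29), with Car9 5.07-fold higher and the glucose transporter Slc2a1 2.55-fold and Ankrd37 2.39-fold lower. Antigen presentation genes were higher in 3 and lower in 0 of 7 (median 0.90), Ifitm3 by 3.29-fold, H2-D1 by 2.61-fold and H2-K1 by 2.43-fold, all of them higher in non-skeletal cells. Inflammatory genes were higher in 2 and lower in 0 of 5 (median 0.33), with Il1r1 4.99-fold and Cxcl1 2.13-fold higher. DNA maintenance and senescence genes were higher in 2 and lower in 2 of 7 (median 0.24), with Cdkn1a 2.21-fold higher and Lmnb1 3.52-fold lower. Of all lists, 11 had a median outside 95% of random lists, of which FGF and jaw patterning did not with equal weight per class. No haemoglobin gene was measured in skeletal cells.

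In the sum over all skeletal cells, cell cycle genes were the clearest group lower at P0, with 0 higher and 17 lower of 25 (median log2 −1.16, below all random lists). With equal weight per class 5 of 25 were lower and 0 higher (median −0.44). Mcm3, Rrm2 and Bub1 were 4.02-fold, 3.95-fold and 3.53-fold lower. After thinning to 3000 UMIs, 28.5% of 3971 skeletal cells at E16.5 held a UMI of the proliferation genes Mki67 or Top2a (27.1 to 30), 15.1% of 3633 at P0 (14.0 to 16.3) and 6.86% of 6864 at 13w (6.27 to 7.49). Without thinning the shares were 48.0%, 29.9% and 11.3%, at median depths of 17818, 17889.5 and 10876 UMIs, and thinning dropped 119, 117 and 243 cells. As types that should cycle little, the chondrocyte cluster led by Col10a1 had a thinned share of 1.05% at E16.5 (median depth 46514 UMIs) and 1.88% at P0 (35852.5), and the larger hypertrophic chondrocyte cluster 0.917% at 13w (24875.5). Between P0 and 13w no order is read, because Mki67 stood at 70.6 CPM and 73.5 CPM and cell cycle genes were higher in 0 and lower in 2 of 23 (Mcm5 3.22-fold and Mcm3 2.39-fold lower), with a median of −0.17 that takes the opposite sign with TMM factors. With equal weight per class 23 of 24 were lower (median −1.42). The chondrocyte family had thinned shares of 3.03%, 2.87% and 1.57%, the surface and fibroblast family 29.4%, 21.5% and 1.97%, and unnamed cells 37.3%, 24% and 10.4%. The adult cycling clusters, of 198 and 166 cells, are unnamed, so the family shares at 13w leave them out.

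**Figure D2:**
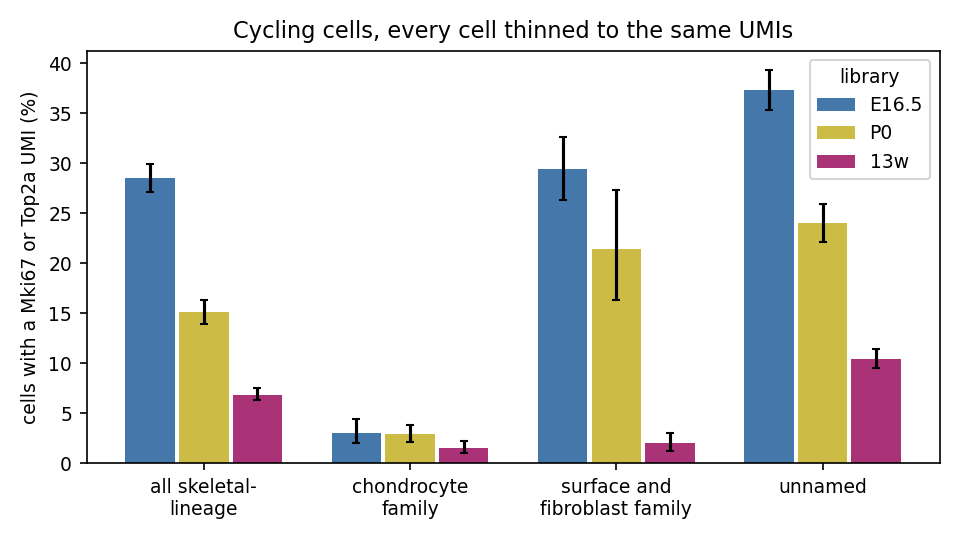
Share (percent) of thinned cells with a UMI of Mki67 or Top2a per library, for all skeletal cells, the 2 families and unnamed cells, with 95% Clopper-Pearson intervals. All skeletal cells lie at 28.5% at E16.5, 15.1% at P0 and 6.86% at 13w, and the chondrocyte family between 3.03% and 1.57%.

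The adult condyle differed from the newborn one by less transcript of fetal growth genes and more of adult matrix, bone-like and immune-related genes. The imprinted growth genes Igf2, H19, Mest, Dlk1 and Cdkn1c, and Gpc3, a binding partner of growth factors, were far lower at 13w. The adult cells had more transcript for the cartilage intermediate layer genes Cilp and Cilp2, the matrix proteins Spon2, Ecm1 and Dpt, the bone proteins Bglap and Ibsp, the collagenase Mmp13, and the surface lubricant Prg4. Genes of antigen presentation and of the innate immune response, such as H2-D1 and Cxcl1, were also higher. The circadian repressor Nr1d1 was higher too, and the hour of tissue collection is not given in the sources used here. Of 8024 genes measured, 652 were higher and 676 lower. The higher genes were 49.1% of the calls, against 66.4% with TMM factors and 67.7% with median-of-ratios factors, which move the median log2 ratio up by 0.19 and 0.20.

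Among genes with at least 100 CPM in the higher library and no higher level in its other cells, Cilp2 had the highest ratio, at 132 CPM at 13w against 0.851 at P0 (log2 7.27, 6.95 to 7.62), followed by Spon2 at 905 against 7.01, Bglap at 192 against 1.60 and its neighbour copy Bglap2 at 60.9-fold. Ecm1 was 52.8-fold, Ecm2 38.7-fold, Dpt 36.6-fold, Nr1d1 34.5-fold, Igfbp6 31.6-fold and Fxyd2 29.8-fold higher. Igf2 was lowest in ratio among the same genes, at 5.20 CPM against 1062 (log2 −7.67, −7.80 to −7.55), then H19 at 9.77 against 1872, the fetal cartilage matrix gene Matn1 by 134-fold, Gpc3 by 110.2-fold and Mest by 48.9-fold. Plaat3, Cdkn1c, Rras2, Matn4 and the Wnt antagonist Frzb were lower by 18.5-fold, 13.4-fold, 12.4-fold, 10.2-fold and 9.04-fold.

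The imprinted growth network was lower as a group, with 0 higher and 12 lower of 13 (median log2 −3.75, below all random lists). Dlk1 was 463-fold lower, and Igf2bp1, with 1 count at 13w, had a log2 ratio of −10.14 (counting interval −15.44 to −7.66). Igf2 and H19 were also lower at 13w in the non-skeletal cells, at 1.58 against 644 CPM and 0.264 against 1191 CPM. Those cells differ in kind between the libraries, with 33 endothelial and 49 mural cells at P0. At 13w they include 156 neutrophils, 89 cells of the cluster named monocyte and 69 B cells. The IGF axis went both ways, 4 higher and 4 lower of 11 (median −0.23), with Igfbp6 and Igfbp7 (10.2-fold) higher and Igfbp2 199-fold lower.

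Matrix groups parted at 13w. Joint surface genes were higher in 9 and lower in 1 of 14 (median 1.93; 4 and 1 of 14 with equal weight per class, median 0.59). Within the surface family 4 were higher and 4 lower of 14 (median −0.17), and in chondrocytes 4 were higher and 1 lower of 9 (median 0.54). The sum over skeletal cells had Cilp 202-fold higher and Prg4 at 31.9 against 5.11 CPM. Fibrous matrix genes were higher in 13 and lower in 4 of 25 (median 1.37), with Dcn 11.1-fold higher and the elastic fibre genes Fbn2 and Eln 317-fold and 9.99-fold lower. Within chondrocytes 11 were higher and 2 lower of 21 (median 1.12), but within the surface family 8 were higher and 6 lower of 25, with a median (0.19) inside the random range. Hypertrophy and mineralisation genes were higher in 8 and lower in 3 of 16 (median 1.0), with Mmp13 20.6-fold and Ibsp 11.0-fold higher. Cartilage matrix genes were higher in 5 and lower in 8 of 22 (median −0.62; 6 and 4 of 21 with equal weight, median −0.18), with Cytl1 26.3-fold and Chad 17.0-fold higher. Proteases and inhibitors were higher in 6 and lower in 1 of 12 (median 1.0), with Mmp3, which had 4 counts at P0, at log2 9.83 (8.47 to 11.71), Adamts2 7.32-fold higher and Mmp16 4.69-fold lower.

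Signalling lists were mixed. Hedgehog and Pthlh genes were higher in 3 and lower in 0 of 10 (median 0.30), namely the hedgehog-binding Hhip by 4.42-fold, Gas1 by 3.55-fold and Cdon by 2.69-fold, and Hhip goes the other way with equal weight per class, where 0 of the list were higher and 2 lower of 12 (median −0.07). With thinned cells the list's median is likewise below 0 (−0.10). Wnt genes were higher in 4 and lower in 7 of 19 (median −0.40), with the antagonist Dkk1 26.1-fold higher and the effector Lef1 11.0-fold lower. BMP and TGF-beta genes were higher in 3 and lower in 8 of 27 although their median was 0.37, with Bmp7 and Fst 64.4-fold and 38.3-fold lower and Ltbp2 14.6-fold higher. FGF genes were higher in 3 and lower in 1 of 11 (median 0.53), with Dusp6, Fgf1 and Spry4 10.2-fold, 7.84-fold and 3.96-fold higher. Notch genes were higher in 1 and lower in 0 of 3 (median −0.11, of opposite sign with TMM factors), with Hes1 2.06-fold higher. Progenitor candidates were higher in 6 and lower in 2 of 21 (median 0.64), with Ly6a 23.2-fold and Prrx2 4.19-fold higher and Axin2 4.09-fold lower, and in 8 and 9 of 26 with equal weight per class (median 0.41). Jaw patterning transcription factors were higher in 2 and lower in 0 of 9 (median 0.62), Barx2 by 10.1-fold and Shox2 by 3.11-fold, with a median of 0.05 when classes weigh equally.

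Stress, metabolic and immune groups differed in size. Inflammatory and complement genes were higher in 7 and lower in 0 of 7 (median 2.36), with Cxcl1 12.1-fold, Serping1 8.95-fold and Cxcl14 6.25-fold higher. Antigen presentation genes were higher in 6 and lower in 1 of 9 (median 1.55), with H2-D1 19.4-fold and H2-T23 15.8-fold higher and Ifitm1 43.0-fold lower. H2-D1 stood at 295 CPM at 13w, below the 919 CPM of the non-skeletal cells. Immediate early and heat shock genes were higher in 9 and lower in 0 of 20 (median 0.97), with Fosl1 8.06-fold, Hspa1a 3.43-fold and Hspa1b 3.29-fold higher. Mechanoresponse genes were higher in 3 and lower in 0 of 14 (median 0.35), Ccn4 by 2.63-fold, Ptgs2 by 2.47-fold and Tnfrsf12a by 2.06-fold. Glycolysis genes were higher in 3 and lower in 3 of 19 (median 0.00), with Ankrd37 5.83-fold and Pfkp 3.66-fold higher and Car9 7.43-fold lower. DNA maintenance and senescence genes were higher in 2 and lower in 2 of 7 (median 0.30), with Cdkn1a 2.97-fold higher and Ccnd1 2.96-fold lower. Of the myeloid granule genes 2 were measured, too few for a median. S100a9, with 1 count at P0, stood at 22.0 CPM at 13w and S100a8 at 17.1 CPM, against 40565 and 32178 CPM in the non-skeletal cells. In all, 14 lists had a median outside 95% of random lists. Of these, cartilage matrix, BMP and TGF-beta (0.04), jaw patterning and mechanoresponse (0.12) lay inside that range with equal weight per class. With thinned cells FGF (0.28), progenitor (0.16), jaw patterning (0.38) and mechanoresponse (0.28) did.

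**Figure D3:**
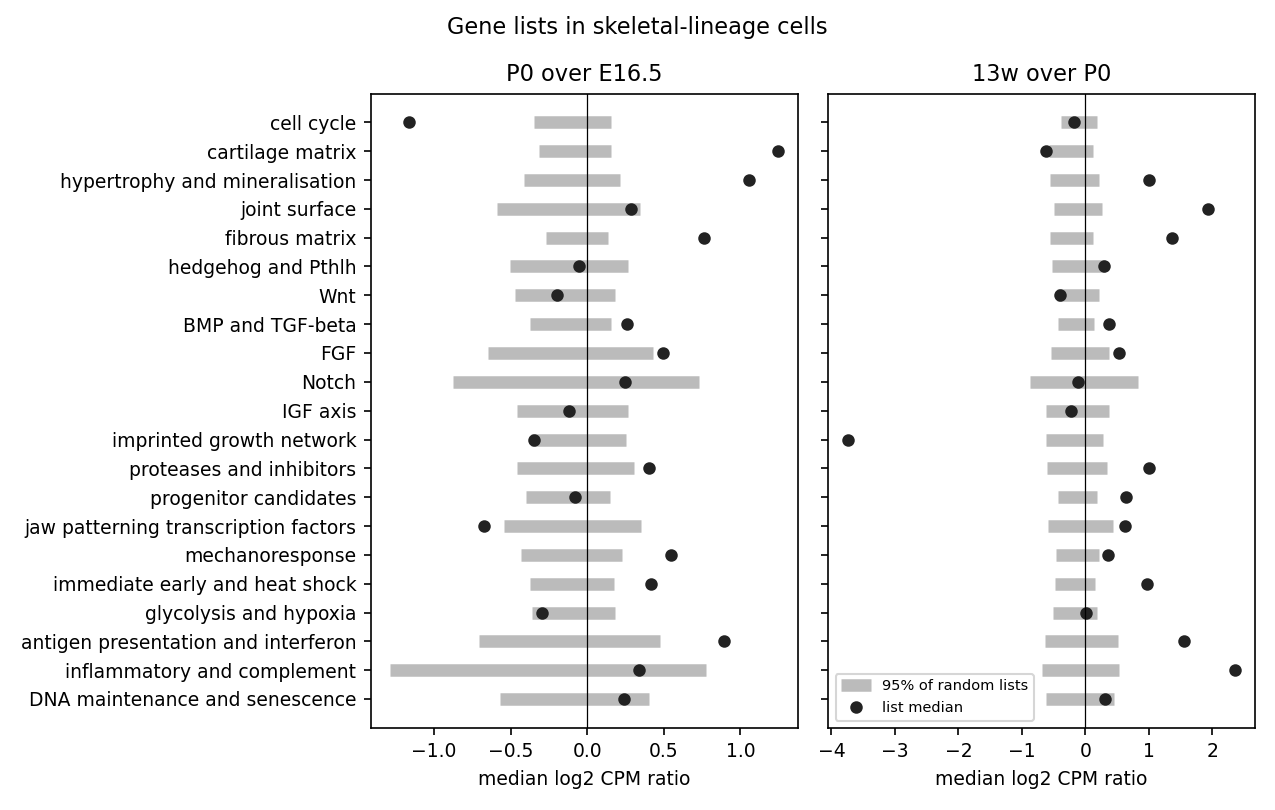
Median log2 CPM ratio of each gene list in skeletal-lineage cells for P0 over E16.5 and 13w over P0, against the range of 95% of 10000 expression-matched random lists. Cell cycle genes (−1.16) and cartilage matrix genes (1.25) lie at opposite ends in the first comparison, and imprinted growth genes (−3.75) and inflammatory genes (2.36) in the second.

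From E16.5 to 13w, 939 genes were higher and 1466 lower of 8403 (39.0% higher, against 63.4% with TMM factors and 63.8% with median-of-ratios factors, which move the median by 0.33 and 0.34). Of the genes called in both steps, 86 were higher in both, 65 lower in both, 94 higher then lower and 41 lower then higher.

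Chondrocytes of P0 and E16.5 differed less in cartilage matrix genes than whole skeletal sums did, and differed in glycolysis and fibrous matrix genes. P0 chondrocytes had less transcript for the glucose transporter Slc2a1, the hypoxia gene Bnip3 and the glycolytic enzyme Pfkl, and more for fibrous collagen Col1a1 and the tendon transcription factor Scx. The adult chondrocyte family, which includes a cluster that also expressed bone genes, had more transcript for the matrix proteins Sparc and Col1a1 and for the Wnt antagonist Dkk1. It had far less for Bmp7. At P0 against E16.5, 368 genes were higher and 324 lower of 7507. Fibrous matrix genes were higher in 12 and lower in 0 of 20 (median 1.22), with Col1a1 at 3586 against 945 CPM. Glycolysis and hypoxia genes were higher in 1 and lower in 4 of 19 (median −0.71, below all random lists), with Slc2a1 at 33.4 against 134 CPM. Of 9 cell cycle genes 5 were lower and 0 higher (median −1.27).

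At 13w against P0 in chondrocytes, 533 genes were higher and 929 lower of 7514 (36.5% higher, against 60.2% with TMM factors and 63.0% with median-of-ratios factors, median shifts 0.26 and 0.29). Sparc stood at 70733 against 6963 CPM, Dkk1 at 38.7 against 0.693, and Bmp7 at 0.881 against 37.7. These values are not split by cluster. The adult family pools its larger cluster with one of 718 cells whose leading genes include Bglap, Bglap2 and Alpl. An unnamed adult cluster of 1930 cells, led by Comp, Fmod and Spon2, lies outside the family. A difference within cartilage cells is thus not separated from this makeup. Hypertrophy and mineralisation genes were higher in 7 and lower in 2 of 16 (median 0.77), a list that shares 10 genes with the markers that named these clusters. Imprinted genes were lower in 10 and higher in 0 of 12 (median −3.42). Immediate early and heat shock genes were higher in 9 and lower in 0 of 20 (median 0.95). Glycolysis and hypoxia genes were higher in 4 and lower in 3 of 20, with a median (−0.11) inside the random range and of opposite sign with TMM factors. The P0 and adult cells of this family lie in different clusters, as named above. The adult ones were named hypertrophic, but the cluster holding 710 P0 cells, named chondrocyte, was also led by Col10a1 of the hypertrophy list. The difference in name is thus not a clean difference in hypertrophy.

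Surface and fibroblast cells had more of several mechanical response transcripts at P0 than at E16.5, and single hedgehog pathway genes differed in both steps while the list did not stand apart. At P0 they had more transcript for Ccn2, for Procr, a receptor used as a stem cell marker elsewhere, for the cell cycle inhibitor Cdkn1a, and for the hedgehog targets Gli1, Ptch1 and Hhip. They had less for the growth factor Fgf10 and for Gas1. Procr was not particular to these cells. After thinning at P0 it was found in 15.6% of 32 endothelial cells, against 6.44% of 233 surface and fibroblast cells. In the adult, the antigen presentation gene H2-K1 and the complement gene C1s1 were higher, and the growth factor Bmp4 and the hedgehog targets were lower. At P0 against E16.5, 580 genes were higher and 1160 lower of 8894 (33.3% higher, against 50.7% with TMM factors and 51.9% with median-of-ratios factors, shifts of 0.18 and 0.20). Ccn2 stood at 321 against 15.6 CPM, Procr at 42.7 against 1.89, Gli1 at 65.0 against 16.1, Ptch1 at 203 against 49.7 and Fgf10 at 0.769 against 24. Mechanoresponse genes were higher in 6 and lower in 0 of 14 (median 0.76). Immediate early and heat shock genes, which handling can raise, were also higher in 8 and lower in 0 of 19 (median 0.90), and inflammatory genes in 4 and 0 of 5 (median 1.36). Hedgehog and Pthlh genes were higher in 4 and lower in 1 of 11, with a median (−0.10) inside the random range whose sign depends on scaling. The family lies mainly in different clusters at these stages, of 688 cells at E16.5 and 194 at P0, and the hedgehog values depend on which clusters were named. An unnamed E16.5 cluster of 391 cells had Gli1 at 70.1, Ptch1 at 305 and Hhip at 134 CPM, of which Gli1 and Ptch1 are at or above the P0 family.

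At 13w against P0 in the surface and fibroblast family, 1009 genes were higher and 1083 lower of 8636, with a median shift of 0.14 under TMM. Cell cycle genes were lower in 24 and higher in 0 of 25 (median −5.00), but the P0 family includes 38 cells of a cycling cluster and the adult cycling clusters are unnamed and outside it. Hedgehog and Pthlh genes were lower in 5 and higher in 1 of 11 (median −0.28, inside the random range). Antigen presentation genes were higher in 8 and lower in 1 of 10 (median 2.78), and imprinted genes lower in 13 and higher in 0 of 13 (median −3.64). H2-K1 stood at 92.6 against 5.0 CPM, C1s1 at 59.1 against 1.92, Bmp4 at 22.3 against 152, Gli1 at 18.9 against 65.0 and Ptch1 at 94.1 against 203. The P0 side rests on 245 cells, the adult side is a single cluster with a different name, and the adult class nearly disappears under some cell filters.

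Within each library, the 2 families differed in several signalling and metabolic genes, chosen here after their values were seen. Surface and fibroblast cells carried the growth plate signal Pthlh, the hedgehog co-receptor Gas1 and the growth factor Igf1, and at P0 and 13w also Procr, which was at 1.89 CPM at E16.5. At 13w Procr was found in only 1.88% of 1013 thinned surface and fibroblast cells. Chondrocytes carried the transcription factor Foxa2, the ecto-nucleotidase Nt5e, the channel Trpv4 and glycolysis genes. The hedgehog-binding gene Hhip was higher on the surface side at E16.5 and P0. At 13w it was higher in the chondrocyte family through its smaller cluster of 718 cells (170.1 CPM), while the larger one of 1092 cells equalled the surface cluster (both 33.0 CPM). None of these genes was used to form the clusters unless it is a cell type marker. Pthlh stood at 86.0 CPM in surface and fibroblast cells against 0.158 in chondrocytes at E16.5, 193 against 0.109 at P0 and 38.1 against 0.0489 at 13w. Gas1 stood at 566 against 1.77, 165 against 0.967 and 270 against 4.18. In the opposite direction, Foxa2 stood at 11.8 CPM in chondrocytes against 0.198 at E16.5, 29.5 against 1.54 at P0 and 40.5 against 0.544 at 13w. It was uneven within the family, at 21.2 and 0.899 CPM in the E16.5 clusters of 383 and 434 cells, 50.6 and 11.0 in the P0 clusters of 710 and 852, and 53.9 and 5.46 in the 13w clusters of 1092 and 718. Nt5e stood at 121 against 4.27, 331 against 16.2 and 277 against 120. At 13w Nt5e was also at 260 CPM in an unnamed cluster of 1930 cells, between the chondrocyte clusters of 1092 cells (305 CPM) and 718 cells (204 CPM). It was thus not particular to named chondrocytes in the adult library. Among single clusters, Pthlh was also high in an unnamed E16.5 cluster of 391 cells (124 CPM), above the named surface clusters of that stage.

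**Figure D4:**
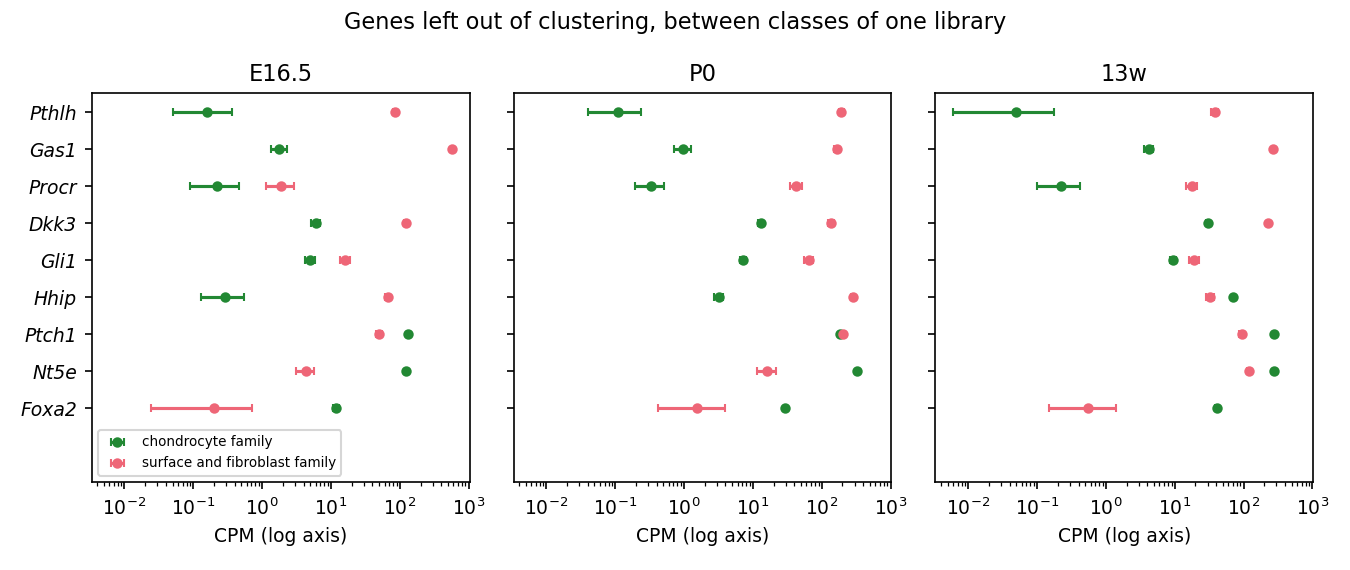
CPM (log axis) of 9 zonal and progenitor genes in the chondrocyte family and in the surface and fibroblast family in each library; the genes were chosen after their values were seen. Pthlh and Gas1 lie on the surface side in every library, Foxa2 and Nt5e on the chondrocyte side, and Hhip lies on the chondrocyte side at 13w (71.1 against 32.9 CPM), through 1 of its 2 clusters.

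By list, glycolysis and hypoxia genes were higher in chondrocytes for 14 and in surface cells for 0 of 18 at E16.5, and for 11 and 1 of 19 at 13w. IGF axis genes were higher in surface cells for 10 and in chondrocytes for 1 of 12 at E16.5, and for 7 and 0 of 10 at 13w. Jaw patterning transcription factors were higher in surface cells for 7 of 9 at E16.5, 8 of 9 at P0 and 6 of 8 at 13w, and in chondrocytes for 0. Progenitor candidates were divided, with 5 higher in chondrocytes and 8 in surface cells of 14 at E16.5, and 4 and 9 of 16 at 13w. Among signalling lists, Wnt genes were divided, 7 and 9 of 18 at E16.5. FGF genes were higher in chondrocytes for 3 and in surface cells for 6 of 10 at E16.5, and for 4 and 4 of 11 at P0. BMP and TGF-beta genes were higher in chondrocytes for 8 and in surface cells for 15 of 30 at E16.5, and for 3 and 15 of 27 at 13w. Hedgehog and Pthlh genes were mostly higher in surface cells, 9 against 1 in chondrocytes of 10 at E16.5. These counts between families were set against neither random lists nor other scalings. In every library most lists had a median on the surface side, so a lean to that side is not particular to the lists named here.

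As shares of cells thinned to 3000 UMIs, Pthlh was found in 20.2% of surface and fibroblast cells at E16.5 (17.5 to 23.1), 39.5% at P0 (33.2 to 46.1) and 8.79% at 13w (7.11 to 10.7). At that depth it was found in 0 of 825 chondrocytes at E16.5, 0 of 1498 at P0 and 0 of 1789 at 13w. The Clopper-Pearson intervals allow shares of cells with a UMI among 3000 of up to 0.446%, 0.246% and 0.206%. Without thinning, 0.600%, 0.255% and 0.110% of chondrocytes held a UMI. Without thinning the surface shares were 44.9%, 65.3% and 15%, at median depths of 11624, 9669 and 6136.5 UMIs against 40041, 35530 and 20606.5 in chondrocytes. Thinning dropped 46, 12 and 67 surface cells. Foxa2 was found in 2.30%, 7.21% and 8.11% of thinned chondrocytes, and in 1 of 823, 1 of 233 and 1 of 1013 surface cells, fewer than the 3 counts taken as the floor. Its unthinned chondrocyte shares were 22.7%, 38.6% and 34.1%, and thinning dropped 9, 69 and 23 chondrocytes.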

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

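Among the genes picked by the fixed rule, a pair went opposite ways between P0 and 13w in the 2 cell families, with ratios of at least 2-fold in both. Genes outside that rule were not searched for such opposite ratios. Hhip, which binds hedgehog ligands, was higher at 13w in chondrocytes (log2 4.46) and lower in surface and fibroblast cells (log2 −3.12). Matn4, a matrix protein gene, was lower in chondrocytes (log2 −3.49) and higher in surface and fibroblast cells (log2 1.31). For Hhip the adult chondrocyte value comes mostly from a cluster of 718 cells at 170.1 CPM, against 33.0 CPM in the larger one. Unnamed adult clusters of 1930, 1836, 198 and 166 cells held Hhip at 78.5, 94.4, 173 and 110 CPM. The contrast between families thus depends on which clusters were named. The difference between families was not tested, since each family has 1 library per stage, and no explanation for it was tested. The adult surface class also depends on cell filters, as given under processing.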

How the results depend on the processing

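No paired analysis was possible because each stage has 1 library and no result comes from a test. The alternative without cycling clusters was chosen after seeing the data. Under it all 14 gene counts stayed within 1.5 times the reported ones. So did all 14 with mean per-cell CPM and all 6 with equal weight per class. Chondrocyte counts could not change without cycling clusters, because no cycling cluster lies in that family. Similar counts can hold different genes. With equal weight per class at P0 against E16.5, 245 of 458 higher and 340 of 699 lower genes in skeletal cells were called again. At 13w against P0 it was 475 of 652 and 448 of 676. The number of lists outside 95% of random lists stayed within 1.5 times of the reported one under all 4 alternatives run on it. Where no cause is given for a value below, the cause was not tested.

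Of 155 named log2 ratios, 117 left their counting interval with TMM factors, and 132 did with equal weight per class, apart from 3 reversed there. Of the 155, 7 took the opposite sign under some alternative. Of these, 3 were at least 2-fold as reported, all under equal weight per class, Dlk1 (0.51) and Pthlh (1.01) for P0 against E16.5 and Hhip (−0.65) for 13w against P0. That alternative evens out the shares of both families and of the unnamed cells, but not the shares of clusters within each of these groups. For these genes the whole-tissue direction thus depends on the weight given to these groups. The other 4 were Notch pathway genes short of 2-fold. Of 125 list medians, 25 took the opposite sign under some alternative, 13 with TMM factors, 17 with thinned cells, 3 without cycling clusters, and 5 of 42 with equal weight per class. Of these, 1 lay outside 95% of random lists as reported, immediate early and heat shock genes in chondrocytes at P0 against E16.5 with thinned cells (−0.056). Equal weight per class also lowered the number of cartilage matrix genes higher at P0 against E16.5 to 3 of 20 and of cell cycle genes lower to 5 of 25. Leaving out the cycling clusters put the cell cycle median in skeletal cells at −1.83 for P0 against E16.5, −0.71 for 13w against P0 and −2.75 for 13w against E16.5.

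Counts of genes depended on scaling. With TMM factors, 451 genes were lower in skeletal cells at P0 against E16.5, 807 lower at 13w against E16.5, 803 higher and 530 lower in chondrocytes at 13w against P0, and 757 lower in surface cells at P0 against E16.5. With median-of-ratios factors, 446 were lower in skeletal cells at 13w against P0, 794 lower at 13w against E16.5, 824 higher and 485 lower in chondrocytes at 13w against P0, and 753 lower in surface cells at P0 against E16.5. With thinned cells, 543 were lower in chondrocytes at P0 against E16.5. Without genes higher in other cells, which tests fewer genes, 216 were higher and 197 lower in chondrocytes and 384 higher in surface cells at P0 against E16.5.

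The CPM minimum sets how many genes can be called. With 1 CPM the counts higher and lower were 918 and 1636 (P0 against E16.5), 1362 and 1602 (13w against P0) and 1581 and 2764 (13w against E16.5) in skeletal cells. They were 982 and 848, then 1210.0 and 1948 in chondrocytes, and 947 and 1981, then 1574 and 1989 in surface cells, for the first 2 comparisons. With 50 CPM they were 206 and 208, 279 and 254, and 464 and 611 in skeletal cells, 133 and 99, then 220 and 389 in chondrocytes, and 269 and 267, then 381 and 378 in surface cells.

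Shares of classes depended on filtering and clustering. With at least 1000 genes per cell, chondrocytes were 24% (E16.5) and 41.5% (13w), surface cells 27.7% and 1.61%, and skeletal cells 94.1% and 95.6%. With at most 5% mitochondrial UMIs, chondrocytes were 25.5% (E16.5) and 31.4% (13w), surface cells 19.1% and 0.0167%, and skeletal cells 97.7% at P0. With each library clustered alone, chondrocytes were 25.4% (E16.5), 38.1% (P0) and 37.5% (13w), surface cells 8.64%, 7.68% and 12.3%, and skeletal cells 91.5% at E16.5. Without doublet removal, chondrocytes were 29.6% and skeletal cells 94.5% at 13w, and surface cells 16.5% (E16.5) and 5.21% (P0). At resolution 0.5 surface cells were 24% (E16.5) and 1.53% (13w). At resolution 2.0 chondrocytes were 24.2% (E16.5) and 37.5% (13w), and surface cells 28.4% and 9.31%. The adult surface class is thus unstable, and its comparisons hold for the reported clustering.

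Cycling shares were higher in level under both alternatives, at 48.0%, 29.9% and 11.3% without thinning and 61.4%, 36.7% and 20.0% with at least 2 UMIs of the cell cycle list (E16.5, P0 and 13w), where deeper cells and more genes give more chances of a UMI. Depth limits genes under 10 CPM, which were not called, and ratios resting on 1 to 4 counts, such as Igf2bp1 and Mmp3.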

Other observations

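All tests in this part were chosen after the result they bear on was seen. The adult skeletal cells showed more transcript than newborn cells of 3 circadian genes that are usually active in different phases, the repressor gene Nr1d1 and the activator genes Arntl and Npas2. Nr1d1 was 34.5-fold higher at 13w, Dbp 7.47-fold, Arntl 6.55-fold and Npas2 5.11-fold, while Per1 was 2.27-fold and Tef 1.80-fold lower. Arntl, Npas2 and Per1 were looked up after their values could be seen.

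A clock shifted alike in all cells of the adult library, as by the hour of collection, is a candidate explanation. It was tested with the summed counts of Nr1d1, Nr1d2, Dbp, Tef, Per3 and Ciart in non-skeletal cells, which it would place at least 4-fold higher at 13w. The ratio there was 0.777 (counting interval 0.581 to 1.05), against 6.34 in skeletal cells (6.14 to 6.55), and the sum is lowered by Tef and Nr1d2. Nr1d1 itself was 1.79-fold higher there (0.950 to 3.66), far below its 34.5-fold in skeletal cells. Both values fell short of those that a shift acting on all cell types alike would give. The non-skeletal cells were, however, mainly endothelial and mural at P0 and mainly neutrophils, monocytes and B cells at 13w. Nr1d1 also rests on 12 counts there at P0. The ratios thus compare different cell types and cannot decide for or against such a shift. A shift in all cells, a shift in skeletal cells alone and the age difference stay open.

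Immediate early and heat shock genes were higher at 13w in skeletal cells, and the same held in non-skeletal cells. Their summed counts had a 13w over P0 ratio of 1.62 in skeletal cells (1.62 to 1.63) and 1.54 in non-skeletal cells (1.5 to 1.58), with 1.85 in endothelial and 2.78 in mural cells. The non-skeletal ratio met the bound written for a response to handling of the whole library, the skeletal ratio divided by 1.5. The non-skeletal cells differ in kind between these libraries, and the endothelial and mural values rest on 23 and 11 adult cells. A response to handling stays open, and so does age, which differs between the same libraries.

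Most skeletal clusters came from single libraries. In equal draws of 17 thinned cells per library, the median share of nearest neighbours from another library was 38.0% in endothelial cells (29.2 to 45.5) and 34.1% in chondrocytes (26.3 to 43.9), where full mixing gives 68%. In these draws endothelial cells sat apart by library about as much as chondrocytes did. In the full clustering, 2 of 8 clusters of other lineages drew over 90% of their cells from 1 library, and endothelial cells of all libraries shared 1 cluster (48, 33 and 23 cells), which goes the other way. A technical difference between libraries stays open, and with 1 library each it cannot be separated from stage. Unequal depth was tested on the same draws. The 34.1% met, barely, the bound of 34% first written for depth as the cause, but its range spans that bound. The condition that the whole range clear the bound was added after this value was seen, and leaves the test undecided. In draws of 200 cells, a test also added then, thinned chondrocytes reached 23.5% (19.2 to 26.4) against a bound of 33.4%, and 7.13% without thinning (5.05 to 10.1). This argues against unequal depth as the whole cause. Whether it had a part stays open, since thinning also removes signal.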
